A study of Mus musculus with 29 samples.

How the data were processed

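RNA sequencing was performed on the aortic arch of male C57BL/6 mice from a cardiovascular safety study of a sclerostin antibody (Scl-Ab). Sclerostin, the product of Sost, is a secreted inhibitor of Wnt signalling, and romosozumab is an antibody against it used in osteoporosis. Per the labels' protocols, mice lacking apolipoprotein E (ApoE KO) received a subcutaneous pump delivering angiotensin II (AngII; 15.27 mg/mL at 0.11 µL/hr), a model of aortic disease, and then either vehicle or Scl-Ab at 10 mg/kg weekly for 4 weeks. Wild-type (WT) mice received vehicle in both the pump and the injections. The libraries came from satellite animals, and the title of each library carries a number that occurs once in the series. Total RNA of at least 80 ng with an integrity number of at least 7 was used to make stranded mRNA libraries. Of the 29 libraries, 9 were ApoE KO with AngII and vehicle (numbers 1 to 9), 10 were ApoE KO with AngII and Scl-Ab (numbers 10 to 19) and 10 were WT (numbers 20 to 29). Groups and numbers were taken from the labels. The treatment protocol in the labels gives 9 WT mice, while 10 libraries are labelled WT, so n counts libraries and whether each WT library came from its own mouse was not settled. These numbers are not shared between groups. The titles also carry a 4-digit code whose meaning the labels do not give. Its last 2 digits run from 1 to 10 in WT and, in both ApoE KO groups, fall in the ranges 12 to 15 and 27 to 33, where 8 vehicle and Scl-Ab libraries share them. No pairing or block was used in the design.

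Each deposited file held 1 value for each of 51456 gene symbols in 1 library. The deposited values are FPKM-like, meaning that they are scaled by gene length, and the authors' name for the unit (FPKQ) is not spelled out per the file headers. Their scale was checked on the values. For low-valued genes with 1 annotated transcript, the value multiplied by the exon length in kilobases lay on steps of a size common to the library, and 78.2 to 82.0% of low values lay within 0.05 of a whole number of steps. The 85th percentile over genes was 6.99 to 7.30 in every library, while the sum of values ranged from 496126 to 678907. These values are therefore treated as scaled to a common upper quantile and not to library totals. Per the submitters' processing notes, genome build GRCm38 and DESeq2 1.10.1 were used, with no role given. The aligner, the counting method and the annotation are not given in the sources used here.

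From the step sizes, a value of 1 in a gene of 2 kb corresponded to 31.9 to 43.8 fragments (median 39.9), so the libraries had similar depth. Total read numbers are not known. Between 12558 and 13397 genes had a value of at least 1 in a library. The 10 highest genes held 15.3 to 33.6% of the sum of values, and 6 gene models that copy mitochondrial sequence held 9.31 to 27.9%. No 2 libraries of a group were duplicates: the smallest root mean square difference between log2 values was 0.235.

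Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), not with a count model, since counts were not at hand. Genes with a value of at least 1 in at least 9 libraries were tested (13510 genes). All 29 libraries entered 1 fit with 3 group means and a common estimate of the spread per gene. An equal spread in the groups was assumed. The lowest correlation between 2 libraries of a group was 0.961 in WT, 0.917 with vehicle and 0.921 with Scl-Ab. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. A fold change on this scale understates the change of low genes. Genotype and AngII differ together between the vehicle-treated model and WT, so their effects cannot be separated. The range of the title codes also differs between them, and so may anything that goes with it. Gene lists (30, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Lists with fewer than 3 tested members were left out, which removed the T cell list (2 of 20 members tested) and the thymocyte list (2 of 11). The list symbols for 3 genes were mapped to older names, and 1 was not matched. Coordinates and gene types came from GENCODE M21, which is on GRCm38 and matched 45889 of the symbols.

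The named genes were fixed by rule before the data were examined. They are Apoe and Sost, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 in the higher group (Gm and Rik models and immunoglobulin and T cell receptor segments passed over), and the member of each list with the smallest p, with the next 2 members where the list passed. Some were left out of the text for length. Fitting and list tests were tested on simulated data with 50 genes changed at each fold size among 13510. At 1.25-fold, 1.5-fold and 2-fold the shares recovered were 44, 80 and 96% for the model against WT. For Scl-Ab against vehicle they were 46, 82 and 98%. The share of false calls was 6.94% for the model against WT and 5.78% for Scl-Ab against vehicle. Each gene was simulated independently. The simulation therefore does not cover correlation between genes or structure shared by samples, and its shares of false calls need not hold for the real libraries. For single indices, exact two-sided permutation tests were used.

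The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5, 3 other scalings (equal totals, TMM as implemented here, quantile), a fit on only the groups compared, array weights, a fold limit, a threshold of 0.1, a Wilcoxon test and leaving out each library in turn. Chosen after the data were seen were the following: a correction of GC content and length trends per library, which covered 97.9% of tested genes, a clock gene index as a covariate (also with an estimated correlation in camera), and fits by the title codes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.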

Results

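Gene expression was measured in the aortic arch of male mice in 29 libraries: 9 from ApoE KO mice infused with AngII and given vehicle (the vehicle-treated model), 10 from ApoE KO mice infused with AngII and given Scl-Ab, and 10 labelled WT with vehicle. The protocol in the labels gives 9 WT mice, so n = 10 for WT counts libraries. Values are FPKM-like, and means are given with the SD over the libraries of a group. Fold changes and their standard errors (SE) are from limma on log2(value + 1). The depth was similar across libraries: a value of 1 in a gene of 2 kb stood for 31.9 to 43.8 fragments.

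The first comparison asked how the diseased aorta differed from the WT aorta. Apoe (GRCm38 chromosome 7, 19696109 to 19699188) was the largest fall and checks the labels. Its mean was 6.71 ± 1.70 (SD, n = 9) in the vehicle-treated model, 8.39 ± 2.79 (SD, n = 10) with Scl-Ab and 264 ± 65.0 (SD, n = 10) in WT. Higher in the model were 21 of 22 macrophage, 24 of 25 fibrillar matrix, 19 of 25 protease and inhibitor and 22 of 24 chemokine and cytokine genes, and 18 of 22 contractile smooth muscle genes were lower (limma). None of these lists passed camera with an estimated correlation (adjusted p = 0.0527 for the first 4 and adjusted p = 0.449 for the contractile list). Each passed with fry (fry adjusted p at most 0.000132), which does not compare a list with the other genes. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 2.71 ± 1.09 (SD, n = 10) in WT to 637 ± 392 (SD, n = 9), a 153-fold change (log2 7.26, SE 0.30). Sost (chromosome 11, 101962458 to 101967015) was 399 ± 141 (SD, n = 9) in the model and 655 ± 108 (SD, n = 10) in WT, 0.585-fold (limma adjusted p = 0.00459).

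In total, 7255 of 13510 genes differed (3065 higher and 4190 lower in the model, limma adjusted p under 0.05), with a median size of change of 1.32-fold. A change of at least 2-fold was found for 650 higher and 183 lower genes. The direction of the balance depended on scaling: 42.2% of the calls were higher as deposited, 54.0% after TMM scaling and 35.9% after removal of GC content and length trends. Across genes, which are not independent replicates, the rank correlation of a library's deviation from the mean with GC content was 0.0377 to 0.216 in the 10 WT libraries. It was -0.34 to 0.248 in the vehicle libraries, of which 7 of 9 lay below 0, and -0.129 to 0.245 with Scl-Ab, of which 6 of 10 did.

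Of the 22 macrophage genes, 21 rose (22 adjusted over the list alone) and 1 did not pass. Mpeg1, which encodes a pore-forming protein of phagocytes, rose 23.7-fold, and Lyz2, which encodes lysozyme, rose 9.14-fold to 1117 ± 464 (SD, n = 9). The list passed with camera (adjusted p = 7.38e-17) and missed the threshold with an estimated correlation (adjusted p = 0.0527). Cd5l, which encodes a protein secreted by macrophages, was at 123 ± 119 (SD, n = 9) in the model and at 0.014 ± 0.029 (SD, n = 10) in WT. Of 24 chemokine and cytokine genes, 22 rose (camera adjusted p = 8.27e-12; adjusted p = 0.0527 with an estimated correlation). Of 12 leukocyte adhesion genes, 9 rose and 1 fell (camera adjusted p = 3.73e-07; adjusted p = 0.0529 with an estimated correlation), and Vcam1, a receptor for leukocytes on activated endothelium, rose 5.13-fold. Of the 21 interferon response genes, 19 rose (camera adjusted p = 1.37e-07, and adjusted p = 0.293 with an estimated correlation). Among them was Irf7, an interferon regulatory factor, at 2.72-fold. Among 9 neutrophil and mast cell genes 5 rose (camera adjusted p = 0.012; adjusted p = 0.351 with an estimated correlation), and all 3 tested B and plasma cell genes rose (camera adjusted p = 0.0468; adjusted p = 0.178 with an estimated correlation).

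Matrix genes rose together: 24 of the 25 in the fibrillar matrix list were higher (camera adjusted p = 1.31e-11; adjusted p = 0.0527 with an estimated correlation). Col8a1, a short-chain collagen, rose 13.5-fold, Thbs1, which encodes thrombospondin 1, rose 18.1-fold, and Loxl2, a collagen cross-linking enzyme, rose 3.57-fold. Of 25 matrix proteases and inhibitors, 19 rose and 0 fell (camera adjusted p = 3.19e-10; adjusted p = 0.0527 with an estimated correlation). Mmp12, a macrophage elastase, rose 33.3-fold, Ctss, a cysteine protease that degrades elastin, rose to 265 ± 95.3 (SD, n = 9) from 12.8 ± 4.12 (SD, n = 10), and Timp1, an inhibitor of matrix metalloproteinases, rose 7.77-fold. Among 21 osteochondrogenic and calcification genes, 12 rose and 4 fell (camera adjusted p = 0.00598; adjusted p = 0.293 with an estimated correlation), with Comp, a cartilage matrix protein, up 4.52-fold and Tnfrsf11b, which encodes osteoprotegerin, up 3.47-fold.

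Contractile smooth muscle genes fell in 18 of 22 cases, with 1 higher and 3 not passing (camera adjusted p = 0.000352; adjusted p = 0.449 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, fell to 509 ± 113 (SD, n = 9) from 1196 ± 65.2 (SD, n = 10), 0.415-fold, and Lmod1, an actin filament nucleator of muscle, fell to 0.449-fold. The vehicle replicate 1 had the lowest values of both genes, 274 and 59.9. The mean log2 value of the adipocyte genes was 5.86 ± 1.29 (SD, n = 9) in the model and 5.28 ± 0.95 (SD, n = 10) in WT (exact permutation p = 0.273). Over the vehicle libraries it correlated with that of the contractile genes (Pearson's r = -0.923, permutation p = 6.00e-05, n = 9; Spearman's rho = -0.967, permutation p = 0.00018) and with Sost (r = -0.845, permutation p = 0.00452, n = 9; rho = -0.90, permutation p = 0.00223). Over 14 relations the adjusted permutation p for these r was 0.00042 and 0.0158 (n = 9), and without the 2 farthest libraries r was -0.902 and -0.723. Endothelial genes rose in 16 of 21 cases (camera adjusted p = 6.60e-06; adjusted p = 0.322 with an estimated correlation), among them Plvap, a diaphragm protein of fenestrated endothelium, by 2.16-fold. Proliferation genes rose in 16 of 19 cases (camera adjusted p = 2.43e-07; adjusted p = 0.318 with an estimated correlation), with Mki67, a marker of cycling cells, up 2.35-fold. Coagulation and fibrinolysis genes rose in 13 of 18 cases (camera adjusted p = 0.000269; adjusted p = 0.178 with an estimated correlation). Oxidative and endoplasmic reticulum stress genes rose in 13 of 20 cases (camera adjusted p = 4.85e-05; adjusted p = 0.0529 with an estimated correlation), including Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 5.23-fold. Cholesterol handling genes rose in 9 and fell in 3 of 20 cases (camera adjusted p = 0.0303; adjusted p = 0.322 with an estimated correlation). Of these, Abcg1, a cholesterol exporter, rose 6.27-fold, and Apoe itself is a member.

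Wnt antagonists and their receptors moved in both directions: 7 rose, 2 fell and 5 did not pass of 14 (camera adjusted p = 0.0141; adjusted p = 0.318 with an estimated correlation). Frzb and Sfrp1, which encode secreted Frizzled-related proteins, rose 3.38-fold and 3.22-fold, while Sost fell. The Wnt target list did not pass (camera adjusted p = 0.975): 5 members rose, 6 fell and 2 did not pass, and Wisp1 rose 3.41-fold. The other large falls were in Cldn22 (0.172-fold), Tcap (0.190-fold), Vwc2 (0.217-fold), Ppp1r1b (0.231-fold) and Dbp, a clock-controlled transcription factor (0.234-fold, SE 0.50 on the log2 scale). In the oxidative phosphorylation list 0 of 22 genes passed with limma or the Wilcoxon test and 0 had an unadjusted p under 0.05; Cycs, which encodes cytochrome c, was at 1.32-fold (limma adjusted p = 0.15). The adipocyte, cardiac muscle, skeletal muscle, neural, erythrocyte, fibroblast, oxidative phosphorylation, immediate early, renin-angiotensin, elastic fibre and TGF-beta lists did not pass with camera; of these the elastic fibre (fry adjusted p = 0.0121) and TGF-beta (fry adjusted p = 0.0186) lists passed with fry.

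**Figure D1:**
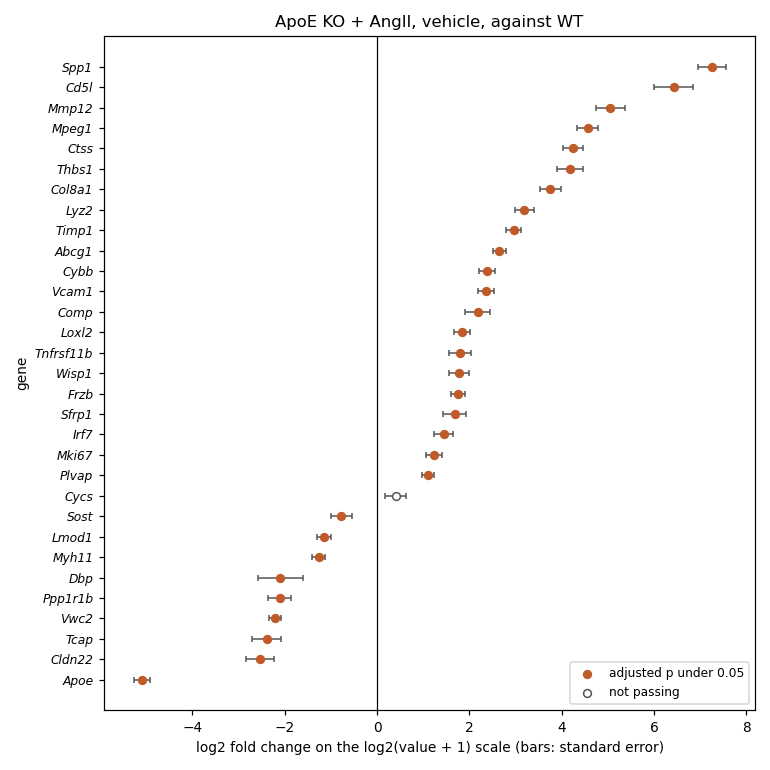
Log2 fold change (x axis, log2 scale) of the 31 genes named here between the vehicle-treated model and WT; points are limma estimates and bars their SE. Cycs (open point) did not pass, and the other genes plotted passed at an adjusted p under 0.05, from Apoe, which fell by 5.10, to Spp1 at 7.26.

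**Figure D2:**
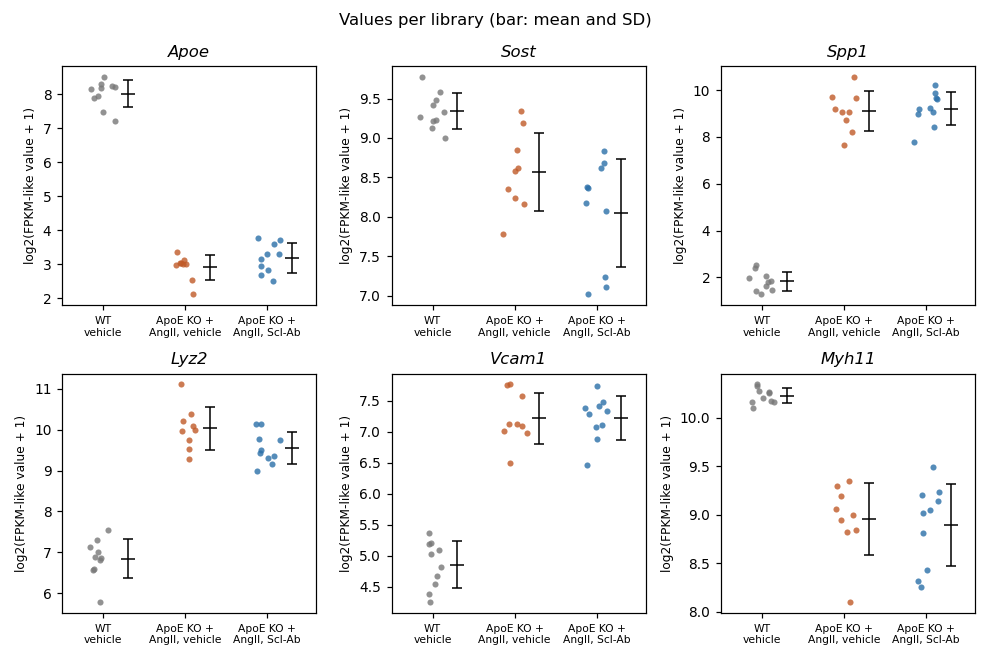
Values per library on a log2(value + 1) axis for 6 genes in the 3 groups; points are libraries and bars the mean and SD. Apoe was low in both ApoE KO groups, and Spp1, Lyz2 and Vcam1 were high in both.

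The second comparison asked what Scl-Ab changed within the model. The largest rises and falls included 5 genes with known roles in the circadian clock, a grouping made after their values were seen. Dbp rose 4.63-fold to 141 ± 37.1 (SD, n = 10) from 42.4 ± 37.2 (SD, n = 9), Per3, a period gene of the clock, rose 3.44-fold, and Hlf, a clock-controlled factor, rose 2.24-fold. Arntl, a core activator of the clock, fell to 0.261-fold and Npas2 to 0.326-fold. Fkbp5, a target of the glucocorticoid receptor, fell to 0.250-fold and Zbtb16 to 0.228-fold. Sost was 289 ± 118 (SD, n = 10) with Scl-Ab and did not pass (0.698-fold, limma adjusted p = 0.141), nor did Apoe (limma adjusted p = 0.381).

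In all, 1005 genes differed (356 higher and 649 lower, limma adjusted p under 0.05), with a median size of change of 1.23-fold, and 11 higher and 18 lower genes changed at least 2-fold. Of the 13510 genes, 3378 had an unadjusted p under 0.05. The count fell to 370 with equal totals per library, where 65.1% of calls were higher against 35.4% as deposited, to 309 in a fit of these groups alone, to 447 with no filter, to 412 with a Wilcoxon test, and to 3 with a clock index as a covariate. That index, the mean log2 value of 8 clock genes minus that of 4 with the opposite phase, was -0.09 ± 1.27 (SD, n = 9) with vehicle and 2.59 ± 0.68 (SD, n = 10) with Scl-Ab. With the Wilcoxon test, the calls of Nppa, Cyr61, Zbtb16, Fkbp5, Errfi1, Fam107a, Nkd2, Synpo2, Nos3, Vwf and Egr3 ended (adjusted p = 0.0542 to 0.233). The count with limma was 547 without vehicle replicate 2, 607 without vehicle replicate 6 and 628 without vehicle replicate 5. The fit of these groups alone, with 309 genes, took the spread from their own libraries and not from WT.

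Cyr61, a matricellular protein, rose 2.36-fold (SD 163 around a mean of 205), and Cys1, which encodes cystin, rose 2.29-fold. Errfi1, a feedback inhibitor of EGF receptor signalling, fell to 0.282-fold and Fam107a to 0.285-fold. For Zbtb16, Fkbp5, Errfi1 and Fam107a, Scl-Ab replicate 10 was far above the rest of its group, at 44.8, 157, 75.3 and 29.2. Endothelial genes fell in 6 of 21 cases and 15 did not pass (7 adjusted over the list alone; camera adjusted p = 0.00243; adjusted p = 0.937 with an estimated correlation). With the Wilcoxon test 1 of the 21 passed. Pecam1, an endothelial adhesion molecule, fell to 0.629-fold and Nos3, the endothelial nitric oxide synthase, to 0.660-fold. Coagulation genes fell in 2 of 18 cases (camera adjusted p = 0.041; adjusted p = 0.937 with an estimated correlation), and in 0 with the Wilcoxon test. Vwf, von Willebrand factor, fell to 0.603-fold (log2 -0.73). Without vehicle replicate 5 its log2 fold change was -0.70 (limma adjusted p = 0.0516) and without Scl-Ab replicate 18 it was -0.66 (limma adjusted p = 0.0511), so the size was similar and the call ended. Thbd was 0.809-fold without passing (limma adjusted p = 0.0798).

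Among 20 oxidative and endoplasmic reticulum stress genes, 4 fell (camera adjusted p = 0.0279; adjusted p = 0.937 with an estimated correlation; fry adjusted p = 0.049), and Hspa5, a chaperone of the endoplasmic reticulum, fell to 0.634-fold. With the Wilcoxon test 3 of the 20 passed. Immediate early genes rose in 2 of 20 cases, and in 0 with the Wilcoxon test (camera adjusted p = 0.000609; adjusted p = 0.937 with an estimated correlation), with Egr3 at 1.91-fold. Cardiac muscle genes rose in 1 of 12 cases, and in 0 with the Wilcoxon test (10 adjusted over the list alone; camera adjusted p = 8.81e-06; adjusted p = 0.937 with an estimated correlation). That gene was Nppa, which encodes atrial natriuretic peptide, at 24.6 ± 37.9 (SD, n = 10) with Scl-Ab and 2.55 ± 5.20 (SD, n = 9) with vehicle; leaving out 14 of the 19 libraries in turn ended its call. Without Scl-Ab replicate 10 (128) its mean was 13.1 ± 11.8 (SD, n = 9), and without vehicle replicate 1 (15.1) it was 0.98 ± 2.37 (SD, n = 8). Tnni3, cardiac troponin I, was at 50.3 ± 42.1 (SD, n = 10) and 15.5 ± 21.6 (SD, n = 9) and did not pass (limma adjusted p = 0.0626); without vehicle replicate 1 (57.5) the vehicle mean was 10.2 ± 15.9 (SD, n = 8).

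The Wnt target list did not pass (camera adjusted p = 0.274), and 1 of its 13 genes, Nkd2, an inhibitor of Wnt signalling, rose 1.34-fold. Of the 14 Wnt antagonists and receptors, 0 passed with limma or the Wilcoxon test and 5 had an unadjusted p under 0.05; Kremen1 was at 0.788-fold (limma adjusted p = 0.0538). Contractile smooth muscle genes did not pass as a list (camera adjusted p = 0.104), and 1 of 22, Synpo2, fell to 0.664-fold. The osteochondrogenic list missed the threshold (camera adjusted p = 0.0516) with 3 members higher and 2 lower (2 in all with the Wilcoxon test), including Bmp6, a bone morphogenetic protein, at 0.539-fold. Adamts15, a protease of the matrix, fell to 0.443-fold. For the macrophage list 0 of 22 genes passed with limma or the Wilcoxon test and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.357), and Ccr2, a chemokine receptor of monocytes, was at 1.55-fold (limma adjusted p = 0.0745). In the fibrillar matrix, proliferation and adipocyte lists 0 members passed with limma or the Wilcoxon test, and 0 had an unadjusted p under 0.05. The chemokine and interferon lists also had 0 passing members with both, and 1 and 3 at an unadjusted p under 0.05. In simulated data for this comparison, 46% of the genes set 25% higher in 1 of the groups were recovered. Those genes were drawn from all tested genes, so the share was not measured for these lists and can be lower there. On the log2 scale the SE was 0.235 for Lox (fibrillar matrix), 0.222 for Ccr2, 0.193 for Il1b (chemokine) and 0.18 for Plin4 (adipocyte). It was 0.137 for Ifit2 (interferon) and 0.0743 for Pcna (proliferation). Changes of 25% can therefore be missed in these lists. With the clock index as a covariate, chosen after the data were seen, 6 further lists passed camera: macrophage, leukocyte adhesion, cholesterol handling and contractile smooth muscle as lower (adjusted p = 0.00497, 1.09e-05, 0.0194 and 0.0402) and fibrillar matrix and proliferation as higher (adjusted p = 0.00636 and 0.00102). None of the 28 lists passed under this covariate with an estimated correlation; for these 6 the adjusted p was 0.856, 0.301, 0.575, 0.906, 0.739 and 0.856. The covariate itself differed between the groups by 2.68 (exact permutation p = 0.000108). It holds Dbp, Per3, Hlf, Arntl and Npas2, which were among the largest changes of this comparison. Its difference is therefore a description and not an independent test.

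**Figure D3:**
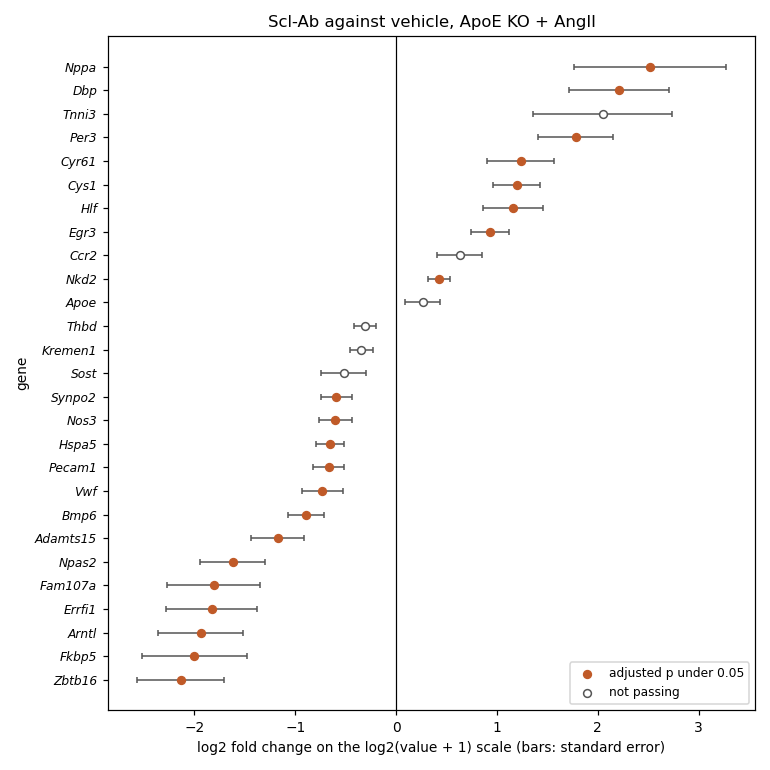
Log2 fold change (x axis, log2 scale) of the 27 named genes between Scl-Ab and vehicle in the model; points are limma estimates, bars their SE, and open points did not pass. The estimates run from Zbtb16, which fell by 2.13, to Nppa at 2.52.

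**Figure D4:**
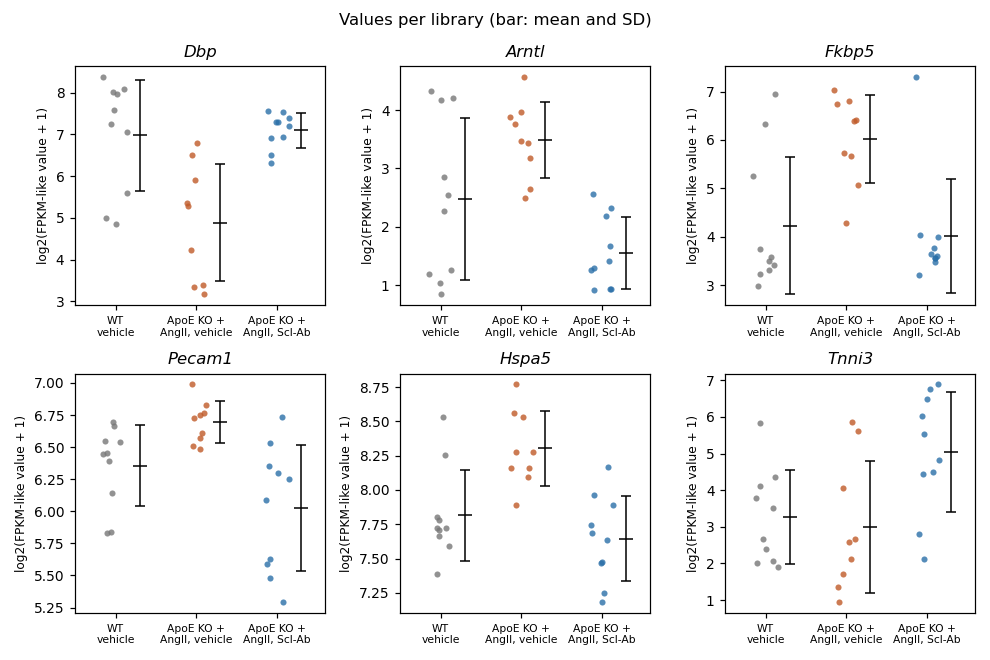
Values per library on a log2(value + 1) axis for 6 genes in the 3 groups; points are libraries and bars the mean and SD. Dbp lay higher and Arntl lower with Scl-Ab than with vehicle, WT libraries spread over both ranges, and 1 Scl-Ab library had a high Fkbp5 value of 157.

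The third comparison set the Scl-Ab group against WT and shares its WT libraries with the first. It called 6808 genes (2681 higher and 4127 lower, limma adjusted p under 0.05), of which 39.4% were higher as deposited and 54.4% after TMM scaling. Mean Spp1 was 655 ± 289 (SD, n = 10) with Scl-Ab, Lyz2 777 ± 216 (SD, n = 10) and Mmp12 32.9 ± 18.9 (SD, n = 10). Mean Sost was 289 ± 118 (SD, n = 10) with Scl-Ab and 655 ± 108 (SD, n = 10) in WT. List tests of this comparison were not part of the plan. With an estimated correlation 4 lists passed, each at an adjusted p of 0.0391: macrophage (20 of 22 higher; camera adjusted p = 1.58e-17), fibrillar matrix (22 of 25 higher; camera adjusted p = 1.81e-13), proteases and inhibitors (18 of 25 higher; camera adjusted p = 4.25e-09) and chemokines (21 of 24 higher and 1 lower; camera adjusted p = 1.81e-13). Contractile smooth muscle genes fell in 18 of 22 cases (camera adjusted p = 1.05e-05; adjusted p = 0.376 with an estimated correlation). Cardiac muscle genes rose in 8 of 12 cases (10 adjusted over the list alone; camera adjusted p = 0.00605; adjusted p = 0.466 with an estimated correlation; fry adjusted p = 0.00947).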

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

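Each value here lay so far from the rest of its group that the gap to the nearest library exceeded Dixon's limit. Of 165 sets of gene and group checked, 14 exceeded it (8.48%), and chance gives about 5%.

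In Scl-Ab replicate 10, 4 of the genes that fell most with Scl-Ab were high: Zbtb16 at 44.8 (others at most 4.84), Fkbp5 at 157 (others at most 15.5), Errfi1 at 75.3 (others at most 27.2) and Fam107a at 29.2 (others at most 2.78). In WT replicate 20, Errfi1 was at 142 (others at most 42.3) and Adamts15 at 24.4 (others at most 12.2). Vehicle replicate 1 had low contractile genes, with Myh11 at 274 (others at least 453) and Lmod1 at 59.9 (others at least 111). Vehicle replicate 5 had Loxl2 at 90.1 (others at most 52.3) and Mki67 at 4.30 (others at most 2.28). Mki67 was at 7.44 in Scl-Ab replicate 13 (others at most 3.39). Scl-Ab replicate 17 had Kremen1 at 5.86 (others at least 9.31) and Cldn22 at 4.77 (others at most 0.825). Cd5l was at 0.0898 in WT replicate 23 (others at most 0.0257), close to 0.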

How the results depend on the processing

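The corrections for GC content and length and for the clock index, and the fits by title codes, were chosen after the data were seen; the other alternatives were fixed before the data were examined. For the model against WT, all alternatives gave 5247 to 8252 genes except a fold limit of 2 (833), and leaving out each library gave 6850 to 7295. For Scl-Ab against WT, the fold limit gave 791 and leaving out each library 6382 to 7674. For Scl-Ab against vehicle, leaving out each library gave 547 to 1223 genes, no filter 447, equal totals 370, a fit on the compared groups 309, the fold limit 29, a threshold of 0.1 1910, a Wilcoxon test 412, removal of GC and length trends 614 (507 shared with the 1005), the clock index as a covariate 3, and both corrections 2; the cause was not tested, except that the fold limit and the threshold count fewer or more genes by construction. The 16 libraries that share the last 2 digits of the title code gave 180 genes without and 7 with these digits as a replicate block, and all 29 libraries with the code range as a covariate 1118. In 2 of the 8 pairs that share the last 2 digits the deviations correlated above 0.1 (-0.461 to 0.572, median -0.17). Of the 8 vehicle libraries, 1 correlated best with its own code. Some of these pairs also differ in the digit after the leading one. These values gave no reason to use a pairing, but they cannot show that the pairs are unrelated, since the meaning of the code is not given. Among the gene lists, an estimated correlation left 0 of 16 for the model against WT and 0 of 5 for Scl-Ab against vehicle (7 and 0 of 28 at an unadjusted p under 0.05 with camera). With fry, the 16 lists of the model against WT also passed (fry adjusted p at most 0.000522). Lists passing for Scl-Ab against vehicle were 1 with fry, 9 with no filter, 3 after quantile normalization, 11 with the clock index (the 5 and 6 others; 0 with the index and an estimated correlation), and 4 to 8 when each library was left out; leaving out vehicle replicate 5, Scl-Ab replicate 13 or Scl-Ab replicate 15 gave 8. For the model against WT the range was 15 to 17, and the clock index with an estimated correlation gave 4. For Scl-Ab against WT, not planned, an estimated correlation left 4 of 18 lists. With the clock index as a covariate, the estimate changed sign for Apoe (-0.22), Dbp (-0.0034) and Hlf (-0.11); Dbp and Hlf are part of that index. The other named genes kept their direction. Depth limits genes near a value of 0.05 in 1 kb, where a library holds about 1 fragment.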

Other observations

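The test of the clock slope within WT and the test of correlation among heart muscle genes within WT were set before their results were seen; the other tests here were chosen after the result they measure was seen. The clock index, the glucocorticoid-responsive genes and the rest of the 15 clock genes were also chosen after the data were seen. The index is the mean log2 value of 8 clock genes minus that of 4 with the opposite phase. It was -0.09 ± 1.27 (SD, n = 9) with vehicle, 2.59 ± 0.68 (SD, n = 10) with Scl-Ab and 1.91 ± 1.76 (SD, n = 10) in WT. Of the 15 clock genes, 6 were higher and 4 lower with Scl-Ab than with vehicle, and 3 were higher and 8 lower in the vehicle-treated model than in WT (limma). Of 10 glucocorticoid-responsive genes, 6 were lower with Scl-Ab than with vehicle and 8 were higher in the vehicle-treated model than in WT. Both sets hold genes that led the changes with Scl-Ab, among them Dbp, Arntl, Zbtb16 and Fkbp5. These counts are therefore descriptions and not independent tests.

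Within WT and within the Scl-Ab group, the clock index correlated with the number in the library title. Over the vehicle group as a whole it did not. Within each group the last 2 digits of the title code rise in the order of this number, so both give the same ordering. The vehicle libraries did show the relation within the code ranges, as given below. In WT, Pearson's r was 0.95 (permutation p = 4.00e-05, n = 10) and Spearman's rho 0.96 (permutation p = 5.00e-05, n = 10). With Scl-Ab, r was 0.82 (permutation p = 0.00362, n = 10) and rho 0.84 (permutation p = 0.00356, n = 10). With vehicle, r was 0.18 (permutation p = 0.636, n = 9) and rho 0.28 (permutation p = 0.463, n = 9). Without the 2 libraries farthest from the median number, r was 0.94, 0.91 and -0.053. Adjusted over 14 relations, the permutation p for r was 0.00042 in WT (n = 10), 0.0158 with Scl-Ab (n = 10) and 0.636 with vehicle (n = 9). Against the last 2 digits of the title code, within the ranges 12 to 15 and 27 to 33, r with vehicle was 0.784 (exact permutation p = 0.0135, n = 9; rho 0.933, exact permutation p = 0.00556; adjusted permutation p for r 0.0271; 0.811 without the 2 farthest libraries). With Scl-Ab it was 0.342 (exact permutation p = 0.319, n = 10, adjusted permutation p for r 0.372) and 0.289 without the 2 farthest libraries. Its rho was 0.422 (exact permutation p = 0.313). The Scl-Ab relation was thus weaker within the ranges and did not pass, but each range holds too few libraries to exclude it. What the numbers and codes stand for is not given in the labels.

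The mean of the adipocyte genes correlated with the contractile mean with r = -0.923 with vehicle (permutation p = 6.00e-05, n = 9; rho -0.967, permutation p = 0.00018), -0.685 with Scl-Ab (permutation p = 0.0316, n = 10; rho -0.661, permutation p = 0.0424) and -0.454 in WT (permutation p = 0.186, n = 10; rho -0.685, permutation p = 0.0349). With Sost, r was -0.845 with vehicle (permutation p = 0.00452, n = 9; rho -0.90, permutation p = 0.00223), -0.523 with Scl-Ab (permutation p = 0.121, n = 10; rho -0.418, permutation p = 0.234) and 0.21 in WT (permutation p = 0.556, n = 10; rho -0.20, permutation p = 0.582). Without the 2 farthest libraries r was -0.902, -0.667 and -0.567 for the contractile mean and -0.723, -0.307 and -0.568 for Sost. Adjusted over the 14 relations, the permutation p for r was 0.00042, 0.0553 and 0.237 for the contractile mean and 0.0158, 0.17 and 0.599 for Sost.

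The first pattern is the set of 1005 genes between Scl-Ab and vehicle. Trends with GC content and length do not account for all of it, since 614 genes were called after their removal, but the median size of change over 993 genes went from 0.29 to 0.26 on the log2 scale and 507 of the calls were shared. A candidate explanation is that the groups were sampled at different circadian phases: of 995 called genes outside the index, 82.0% changed in the direction of their slope on the index within the 10 WT libraries, against 78.2% at the 95th percentile of 1000 reassignments (p = 0.00999). Anything else that varied along the index in WT would give the same result. With the index as a covariate, the median size over the 1005 genes went from 0.29 to 0.18 and the median SE from 0.077 to 0.097, so calls ended through both. An effect of Scl-Ab on the clock genes cannot be told apart from sampling time, because 7 of 10 WT but 2 of 9 vehicle libraries (9 of 19) had an index at or above the lowest Scl-Ab library and no sampling time is given.

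The second pattern is the higher mean of the heart muscle genes with Scl-Ab than with vehicle. As single genes, 1 of 12 passed with limma and 0 with the Wilcoxon test. The list passed camera (adjusted p = 8.81e-06) but not with an estimated correlation (adjusted p = 0.937). The mean log2 value of these genes was 4.46 ± 1.44 (SD, n = 10) with Scl-Ab and 2.91 ± 1.19 (SD, n = 9) with vehicle (exact permutation p = 0.0235, adjusted over 12 tests 0.0469). Against WT, 8 of the 12 genes were higher with Scl-Ab (camera adjusted p = 0.00605; adjusted p = 0.466 with an estimated correlation). Heart muscle carried along with the aortic arch is a candidate source: within WT the median pairwise correlation of the 12 genes was 0.857. Induction by Scl-Ab stays open and cannot be told apart from it. Of the 19 libraries without the antibody, 1 reached the median heart muscle index of the Scl-Ab libraries, which cannot decide between them.

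The third pattern is the lower Sost in the model. A smaller share of contractile smooth muscle RNA is a candidate explanation: the log2 ratio of Sost to the mean of 22 contractile genes differed between vehicle and WT by -0.16 (95% permutation interval -0.41 to 0.09). That interval includes 0 but is too wide to exclude a change of Sost beyond the contractile genes, so the explanations cannot be told apart. The values of Sost and of the contractile genes were known when this test was chosen, so it is a description and not an independent test. The log2 ratio was 0.46 ± 0.45 (SD, n = 10) with Scl-Ab, 0.81 ± 0.31 (SD, n = 9) with vehicle and 0.97 ± 0.20 (SD, n = 10) in WT. Between Scl-Ab and vehicle it differed by -0.35 (exact permutation p = 0.0639, adjusted over 12 tests 0.109). Within groups, Sost and the contractile mean correlated with r = 0.79 with vehicle (permutation p = 0.00951, n = 9; rho 0.87, permutation p = 0.00474), 0.81 with Scl-Ab (permutation p = 0.00761, n = 10; rho 0.61, permutation p = 0.0664) and 0.55 in WT (permutation p = 0.10, n = 10; rho 0.49, permutation p = 0.155). Without the 2 farthest libraries r was 0.85, 0.57 and 0.023, so in WT it rested on those libraries. Adjusted over 14 relations, the permutation p for r was 0.0222 with vehicle, 0.0213 with Scl-Ab and 0.156 in WT.

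Other splits of the same libraries were drawn, 100 for each result with the real one included. For the model against WT, 1 of the 100 splits, the real one, gave 7255 genes, and the highest other gave 4047. Chance is thus an unlikely source of that count, but 100 splits cannot exclude it. The splits also treat all libraries as exchangeable. For Scl-Ab against WT, 1 of 100, the real one, reached 6808 and the highest other gave 4733, with the same limits. For Scl-Ab against vehicle, 3 of 100 reached 1005, the real split and 2 others, a share under 0.05. The highest other gave 3549, several times the real count, so the count of 1005 lies within the range that regrouping gives. What that split separates was not examined. For the number of lists passing camera at the preset correlation, chance is not excluded. Of 100 splits, 21 gave at least the 16 lists of the model against WT (highest other 18). At least the 5 lists of Scl-Ab against vehicle were given by 86 of 100 (highest other 15). Only these counts were compared, so the splits do not test any single list.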
